A study of Mus musculus with 11 samples.

How the data were processed

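RNA from primary microglia of newborn C57BL/6J mice was hybridised as biotin-labelled cRNA to 11 Illumina mouse BeadChip arrays on 2 slides. The deposited scanner table gives, per the file headers, an intensity (the mean bead signal, on the linear scale and not normalized between arrays) for 45281 probes on each array. Beside it the deposited table gives a detection p-value per probe and array. The value table of the authors holds log2 values. Set against the scanner table, those values were log2 signals after quantile normalization over the 11 arrays, moved for each probe by 1 amount on slide 1 and by the opposite amount on slide 2, to within 0.00795 log2 units. The submitters' processing notes name Partek, and further steps are not given in the sources used here. The comparisons used the scanner table, with that of the authors as an alternative, and no genome coordinates.

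Signals were background corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp with an offset of 16, background mean and spread inferred from the detection p-values, quantile normalization, log2). A probe counted as detected at a detection p below 0.01 and was kept when detected on at least 2 of the 11 arrays. Of the probes, 34885 carried 1 gene symbol, 18 several and 10378 none, and 34807 symbols were brought up to date through Entrez identifiers in the RefSeq table. After the filter 15937 probes were left, of which 13765 had 1 gene. Each gene was represented by its probe with the highest mean log2 value, since 3361 genes had more than 1 passing probe. This left 8952 genes. No other passing probe of a named gene was called in the opposite direction.

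A linear model with 1 mean per group was fitted to all 11 arrays by limma (lmFit and eBayes, 7 residual and 3.52 prior degrees of freedom), and 6 contrasts of the 4 groups were tested. Each contrast was adjusted over the 8952 genes by the Benjamini-Hochberg method. A gene was called changed at an adjusted p below 0.05. Fold changes are log2, first group minus second. Where the measured probe of a gene was detected on no array of the lower group, its signal there is only an upper limit, so the change is written as at least N-fold. That bound is the mean of the higher group over the mean, across arrays of the lower group, of the larger of the probe's own value and the lowest value of any detected probe. The number of arrays limits the precision, and the p-values measure only the spread between these samples, since the labels do not say whether replicates are separate cultures or animals.

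Before the data were examined, 25 gene lists, the contrasts, the tests, the filter and the rule for named genes were fixed. The lists held proinflammatory cytokines and effectors, chemokines, interferon-stimulated genes, MHC class I and class II antigen presentation, IL-4 alternative activation, TGF-beta signalling targets, homeostatic microglia markers, lysosomal and damage-associated microglia genes, scavenger and phagocytic receptors, NF-kB pathway and toll-like receptors, cell cycle, glycolysis and hypoxia response, cholesterol biosynthesis, oxidative phosphorylation, NRF2 and oxidative stress response, unfolded protein and heat shock response, extracellular matrix and proteases, and markers of astrocytes, oligodendrocytes, neurons, fibroblasts and mural cells, endothelium, leukocytes and erythroid cells. The 20 lists with at least 5 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with a correlation estimated per list, and fry, were run beside it. The fry p tests whether the genes of a list move, on balance, 1 way, and does not compare the list with other genes. Members past the gene test were counted with p adjusted over all genes and adjusted over the list alone.

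The named genes were, for each stimulus against untreated cells, the 7 largest rises and the 7 largest falls among called genes whose groups did not overlap, up to 4 members of each described list (2 called risers and 2 called fallers, or, with none called, the member with the highest mean signal), and a fixed panel of Nos2, Tnf, Il1b, Il6, Arg1, Chil3, Retnla, Mrc1, Smad7, Tgfbr1, P2ry12 and Cx3cr1. For a stimulus against another, 5 and 5 were taken in place of 7 and 7. For shared calls, the 5 genes with the largest smaller fold change of both comparisons were taken in each class. Genes named outside this rule are marked as chosen after their values were seen.

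The alternatives were no background correction, median scaling in place of quantile normalization, the authors' table, other detection limits and no filter, every probe in place of 1 per gene, slide as a fixed or a random block, the arrays of 1 slide only, replicate number as a block, array weights, robust eBayes with an intensity trend, the arrays of the 2 groups alone, and leaving out each array in turn. Whether replicate numbers pair the samples was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. For IL-4 and untreated cells r was 0.401, 0.444 and 0.261 (all 6 arrays highest with own number), and for other groups -0.156 to 0.485. For LPS/IFNg and TGFb r was 0.235 and 0.369, but 2 pairs whose numbers coincide with slide do not tell pairing from slide.

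Simulated data (200 changed genes among 8952, 5 draws) gave rates the arrays need not share. With IL-4, 64.8% of 2-fold, 97.3% of 4-fold and 98.8% of 8-fold changes were recovered, with 4.40% false calls. With TGFb these were 65.1%, 96.1%, 98.8% and 5.87%, and with LPS/IFNg 53.4%, 97.0%, 99.1% and 4.81%. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.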

Results

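Gene expression was measured on 11 arrays of cultured mouse microglia, the resident macrophages of the brain. The series concerns pro- and anti-inflammatory activation. Cells received IL-4 at 100 U/ml for 48 h (3 arrays), TGFb at 20 ng/ml for 48 h (3 arrays), LPS at 100 ng/ml with IFNg at 20 ng/ml for 16 h (2 arrays), or no stimulus (3 arrays, with no time given). Slide 1 held IL-4 replicates 1 and 2, TGFb replicates 1 and 2 and LPS/IFNg replicate 1. Slide 2 held the third replicates of the stimulated groups and all untreated arrays. The median signal per array was 120.1 to 127. Detected probes numbered 13648 to 14200 with IL-4, 12991 to 13979 with TGFb, 12427 to 12617 with LPS/IFNg and 13869 to 13989 in untreated cells. The first principal component held 61.0% of the variance and set the 2 LPS/IFNg arrays apart from the other 9.

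Arrays of a group correlated across genes at 0.972 to 0.983 with TGFb, 0.982 with LPS/IFNg and 0.968 to 0.983 in untreated cells. IL-4 replicate 1 correlated at 0.945 and 0.954 with the other IL-4 arrays, which correlated at 0.987 with each other. In this array 81 genes lay at least 1 log2 unit above all other 10 arrays, against 0 to 22 in any other array. Of 4 tested markers of fibroblasts and mural cells, 3 lay that far above: Acta2, smooth muscle actin, at 11.5 against 9.27 at most elsewhere, Col1a1, a chain of type I collagen, at 8.32 against 5.12, and Thy1, a surface glycoprotein, at 7.71 against 5.13. Dcn, the proteoglycan decorin, was at 5.21 against 5.80. The interferon-stimulated genes averaged 9.78 in this array, 7.25 and 7.84 in the other IL-4 arrays and 7.72 to 8.35 in untreated cells.

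**Figure D1:**
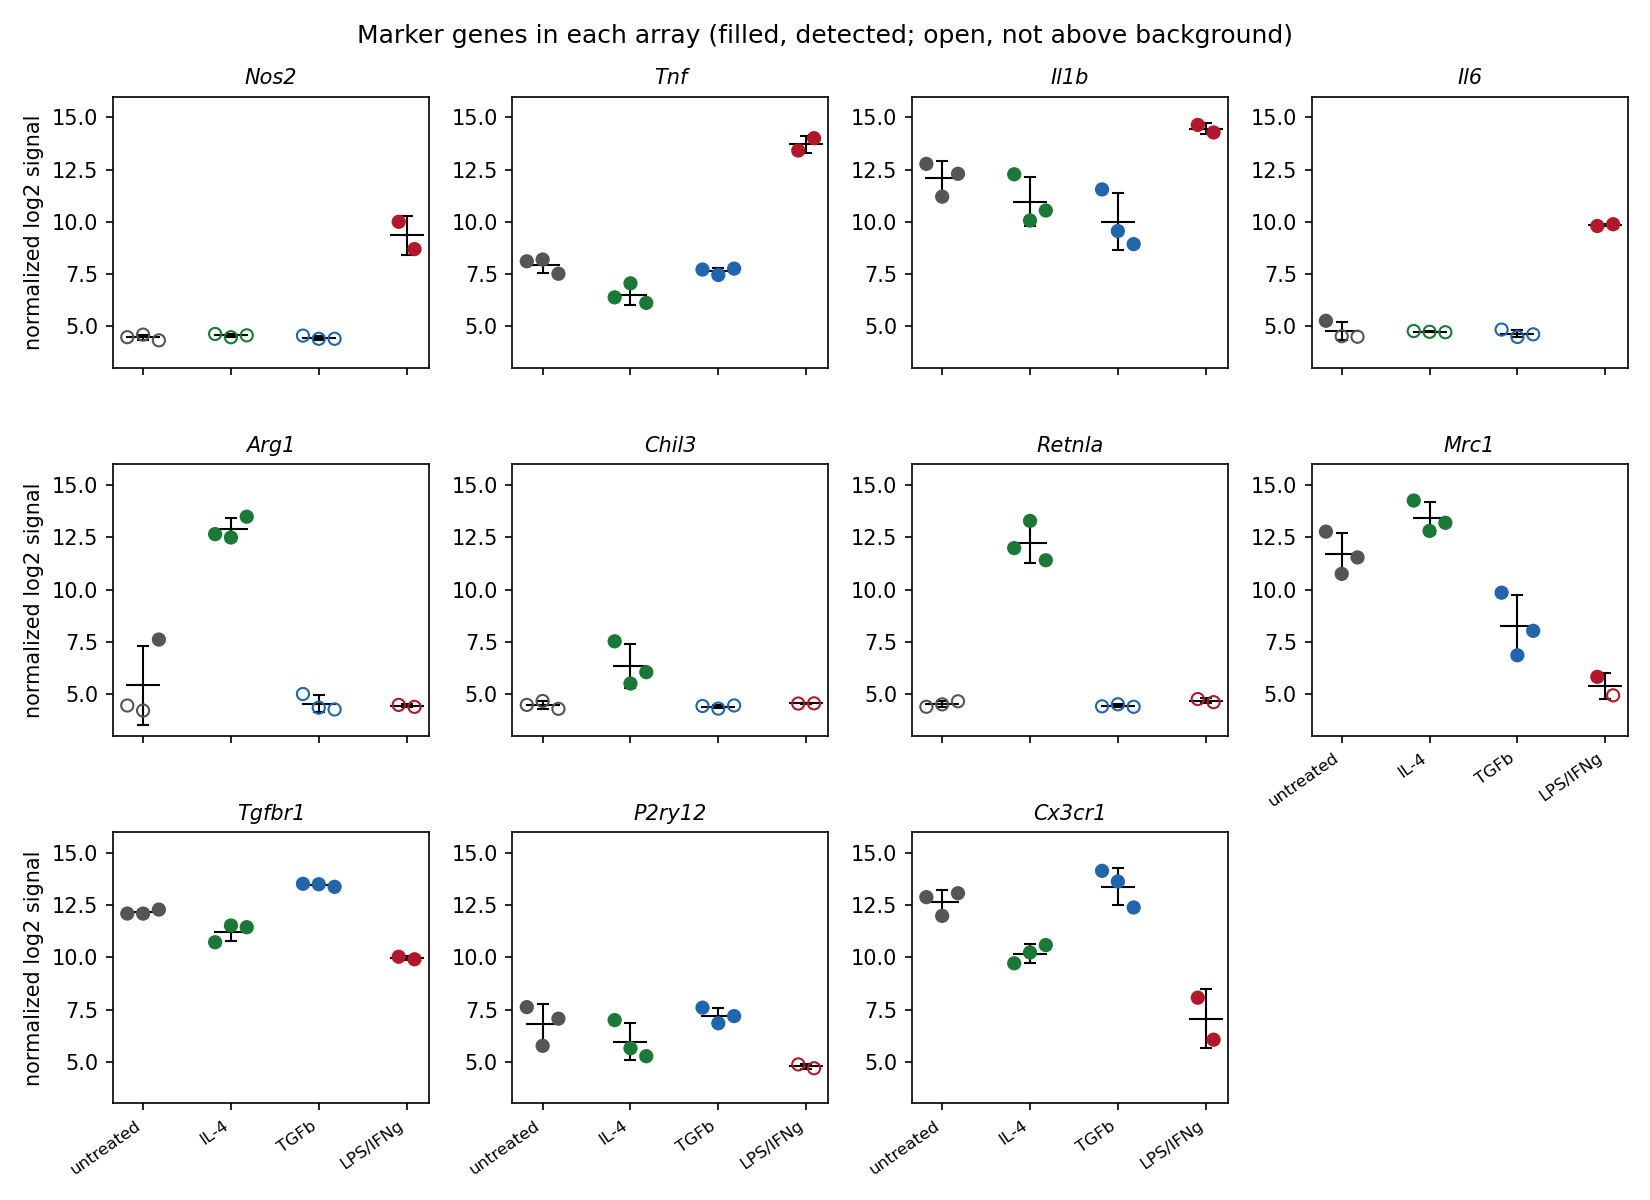
Normalized log2 signal (vertical axis) of 11 panel genes on each of the 11 arrays, by group. Filled points are detected probes, open points are not, and bars give the mean and SD: Arg1 and Retnla stood at means of 12.88 and 12.23 with IL-4, and Nos2 at 9.34 with LPS/IFNg.

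IL-4 against untreated cells asked what an alternative activation stimulus changed. Arg1, the arginase that splits arginine into ornithine and urea, rose by 7.47 ± 0.73 log2 units (SE, adjusted p = 0.000913), from 5.41 ± 1.90 (SD, n = 3), where 1 of 3 arrays detected it, to 12.88 ± 0.53 (SD, n = 3). Retnla, a secreted marker of alternatively activated macrophages, rose at least 143-fold (adjusted p = 5.59e-06), to 12.23 ± 0.97 (SD, n = 3). Slc7a2, a transporter of arginine and other cationic amino acids, rose at least 10.1-fold (adjusted p = 0.00248), Mgl2, a macrophage lectin, at least 15.8-fold (adjusted p = 5.65e-05), and Rnase2a, an eosinophil-type ribonuclease, at least 36.3-fold (adjusted p = 6.07e-05). Ccl24, an eosinophil chemokine detected on 2 of 3 untreated arrays, rose by 3.77 ± 0.62 (adjusted p = 0.0209), and Dusp4, a phosphatase of MAP kinases, by 3.71 ± 0.30 (adjusted p = 0.000283). Il13ra1, a receptor chain for IL-4 and IL-13, fell by 2.61 ± 0.44 (adjusted p = 0.0231). Tlr2, the receptor for bacterial lipoproteins, fell by 2.34 ± 0.42 (adjusted p = 0.0295), the transmembrane protein gene Tmem176a by 2.38 ± 0.42 (adjusted p = 0.0287), and Apoc1, an apolipoprotein, by 1.86 ± 0.37 (adjusted p = 0.0443).

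Of the 35 tested genes of the IL-4 list, 12 rose, 1 fell and 22 were not called (20 and 2 adjusted over the list alone, 7 and 0 by limma with slide blocked). The list was higher, with a median log2 fold change of 1.48 (1.34 with genes at their bounds, 1.41 slide-blocked, 1.51 on slide 2, 1.14 without IL-4 replicate 1). Its adjusted p was 3e-16 by camera, 0.00757 with an estimated correlation and 0.00011 by fry. Of the 26 scavenger and phagocytic receptors, which bind particles and lipids for uptake, 5 fell and 21 were not called (8 falls adjusted over the list alone, 1 with slide blocked and 2 without IL-4 replicate 1). They included Clec4e, a receptor for mycobacterial glycolipid, which fell by 2.23 ± 0.40 (adjusted p = 0.0294; 1 of 3 IL-4 arrays detected it), Cd14, the LPS co-receptor, which fell by 2.03 ± 0.34 (adjusted p = 0.0233), and Cd93, a membrane glycoprotein, which fell by 1.98 ± 0.40 (adjusted p = 0.046). Their median was -0.45 (-0.52 slide-blocked, -0.43 on slide 2), with an adjusted p of 1.7e-06 by camera, 0.0319 with an estimated correlation and 0.00212 by fry.

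Of 32 genes of the NF-kB and toll-like receptor list, 3 fell (Tlr2, Cd14 and Irak3, an inhibitor of toll-like receptor signalling, at -1.09 and named after its value was seen; with slide blocked only Tlr2 passed) and 29 were not called (1 rise and 7 falls adjusted over the list alone). Their median was -0.19 (-0.16 slide-blocked, -0.25 on slide 2; camera adjusted p = 0.00743), adjusted p = 0.423 with an estimated correlation, and adjusted p = 0.0512 by camera without IL-4 replicate 2. No homeostatic microglia marker was called by limma (4 falls adjusted over the list alone), and 29 of 35 had a log2 fold change below 0. Their median was -0.28 (-0.31 slide-blocked, -0.24 on slide 2; camera adjusted p = 8.07e-05, and adjusted p = 0.423 with an estimated correlation). C1qb, a complement chain abundant in microglia, was at 0.01 (adjusted p = 0.985), Cx3cr1, the fractalkine receptor, at -2.47 (adjusted p = 0.0642) and P2ry12, the microglial ADP receptor, at -0.85 (adjusted p = 0.5). Of 29 genes of oxidative phosphorylation, Cyc1, cytochrome c1, rose by 0.70 ± 0.14 (adjusted p = 0.046) and 28 were not called (1 rise adjusted over the list alone, 0 by limma with slide blocked), while 28 of 29 had a value above 0. The median was 0.31 (0.40 slide-blocked, 0.36 on slide 2; camera adjusted p = 7.7e-07), adjusted p = 0.186 with an estimated correlation.

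None of 18 NRF2 and oxidative stress genes was called by limma over all genes or adjusted over the list alone, and their median was -0.31 (-0.26 slide-blocked, -0.20 on slide 2; camera adjusted p = 0.00796). This list had adjusted p = 0.567 with an estimated correlation, and camera gave an adjusted p of 0.366 without IL-4 replicate 1 and of 0.132 without untreated replicate 2. Fth1, the ferritin heavy chain of this list, stood at 15.30 ± 0.06 (SD, n = 3) in both groups. The other 14 lists did not pass. Among them the interferon-stimulated genes had a median of 0.26 (adjusted p = 0.307) and MHC class I genes of 0.28 (adjusted p = 0.0814), and without IL-4 replicate 1 these medians were -0.48 (adjusted p = 2.8e-07, but adjusted p = 0.443 with an estimated correlation) and -0.07 (adjusted p = 0.567). Without it camera also called the cell cycle genes (median 0.27, adjusted p = 0.0011, and adjusted p = 0.574 with an estimated correlation) and astrocyte markers (-0.49, adjusted p = 0.0412, and adjusted p = 0.194 with an estimated correlation), and the matrix genes went from 0.28 (adjusted p = 0.422) to -0.06 (adjusted p = 0.342). With slide blocked camera called the glycolysis genes (adjusted p = 0.00516), TGF-beta targets (adjusted p = 0.0236) and cell cycle genes (adjusted p = 0.0304), which with all arrays in 1 model had medians of -0.26, -0.18 and 0.09. With slide blocked and an estimated correlation these had adjusted p = 0.589, adjusted p = 0.425 and adjusted p = 0.797. Tnf, a proinflammatory cytokine, fell by 1.42 ± 0.27 (adjusted p = 0.0416), and Smad3, a transducer of TGF-beta signals, fell by 1.23 ± 0.22 (adjusted p = 0.0308). Of the panel, the mannose receptor Mrc1 was at 1.74 (adjusted p = 0.31), Il1b at -1.13 (adjusted p = 0.531) and Tgfbr1 at -0.93 (adjusted p = 0.0573). The chitinase-like Chil3 was at least 2.43-fold higher in mean with an adjusted p of 0.0518. Nos2 was detected on no array of either group, and Il6 on 1 of 3 untreated arrays. Median, mean and test differed in sign for chemokines (median 0.00, mean 0.26, tested lower), astrocyte markers (-0.02, 0.03, lower) and oligodendrocyte markers (-0.08, 0.20, lower).

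In total limma called 115 genes, 77 higher and 38 lower, 83 of them at least 2-fold. In all 115 the 2 groups did not overlap, as in 18.5% of all genes (10% by chance). Median scaling gave 78 (63 higher, 15 lower), and without untreated replicate 2 limma called 129, of which 57 were higher and 72 lower. Replicate number as a block gave 184 genes, 106 of them among the 115. On the IL-4 and untreated arrays alone, where same-numbered arrays deviated alike, this block gave 77, of which 46 were among the 115 (chosen after the result was seen). All 17 named genes passed with the first block and all but Cyc1, Il13ra1, Smad3 and Tmem176a with the second, and Mrc1 had adjusted p = 0.0187 and adjusted p = 0.0301, and Chil3 adjusted p = 0.0422 and adjusted p = 0.0998. With slide as a block 29 were called, 28 of them among the 115, and all 115 kept their sign. Within slide 2, where the 1 IL-4 array had no spread of its own and was tested on that of the untreated arrays, limma called 3. Of the 17 named genes that passed, 8 also passed with slide blocked (Arg1, Retnla, Rnase2a, Mgl2, Dusp4, Slc7a2, Clec4e and Tlr2). Whichever array was left out, 6 passed (Arg1, Retnla, Rnase2a, Mgl2, Dusp4 and Slc7a2). The other 11 missed the threshold without some array, at highest adjusted p-values of 0.0693 to 0.169, and 25 genes in all were called without untreated replicate 1 and 32 without untreated replicate 3.

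TGFb against untreated cells asked what the other 48 h stimulus changed. Clec4a1, Clec4b1 and Clec4a3, C-type lectin receptors of myeloid cells, fell, at -4.67 ± 0.52 (SE, adjusted p = 0.00488), -3.49 ± 0.37 (adjusted p = 0.00488) and -3.10 ± 0.28 (adjusted p = 0.00356). Clec4a1 went from 10.75 ± 0.98 (SD, n = 3) to 6.08 ± 0.49 (SD, n = 3), and Clec4b1 was still detected on 1 of 3 TGFb arrays. Igfbp5, which binds insulin-like growth factors, rose by 4.30 ± 0.66 (adjusted p = 0.0182) and Htr2b, a serotonin receptor, by 3.46 ± 0.37 (adjusted p = 0.00488); each was detected on 2 of 3 untreated arrays. Notch4, a Notch receptor, rose by 2.32 ± 0.40 (adjusted p = 0.0282), Cspg4, the proteoglycan NG2, by 2.07 ± 0.31 (adjusted p = 0.0182; detected on 2 of 3 untreated arrays), AU020206 by 2.22 ± 0.43 (adjusted p = 0.0436) and Nrep by 2.26 ± 0.45 (adjusted p = 0.0495). Rgl1, an exchange factor for Ral GTPases, fell by 2.20 ± 0.25 (adjusted p = 0.00488).

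Of 28 TGF-beta signalling targets, 3 rose and 25 were not called (7 rises and 3 falls adjusted over the list alone, 0 by limma with slide blocked, 4 and 2 without IL-4 replicate 1). Pmepa1, a feedback inhibitor of the pathway, rose by 2.36 ± 0.46 (adjusted p = 0.0442), Spsb1, a SOCS box protein, by 1.87 ± 0.31 (adjusted p = 0.0261), and the receptor gene Tgfbr1 by 1.31 ± 0.20 (adjusted p = 0.0185). The median of the list was 0.11 (0.19 slide-blocked, 0.22 on slide 2) and camera did not call it (adjusted p = 0.0734), but did with replicate number as a block (adjusted p = 0.0423, and adjusted p = 0.503 with an estimated correlation). The inhibitor gene Smad7 had 1 probe, detected on 0 of the 11 arrays, and was not tested.

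Of 35 homeostatic microglia markers, 1 rose (Golm1, a Golgi membrane protein, by 1.88 ± 0.32, adjusted p = 0.0261) and 34 were not called (11 rises and 1 fall adjusted over the list alone, 0 by limma with slide blocked, 3 and 1 without IL-4 replicate 1). Their median was 0.45 (0.35 with slide blocked and on slide 2; camera adjusted p = 0.00067), adjusted p = 0.462 with an estimated correlation. Of 11 MHC class II genes, 1 rose (H2-Ob, a chain of the peptide loading regulator, by 1.74 ± 0.25, adjusted p = 0.0173) and 10 were not called (5 rises and 1 fall adjusted over the list alone, 0 by limma with slide blocked). Their median was 0.48 (0.45 slide-blocked, 0.43 on slide 2; camera adjusted p = 0.00443), adjusted p = 0.462 with an estimated correlation. Without untreated replicate 2 camera gave adjusted p-values of 0.2 for the homeostatic markers and 0.18 for MHC class II. Cx3cr1 was at 0.74 (adjusted p = 0.721) and P2ry12 at 0.39 (adjusted p = 0.873).

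Of 18 chemokines, 2 fell and 16 were not called (4 falls adjusted over the list alone, 1 with slide blocked): Ccl9, a monocyte attractant, fell by 3.19 ± 0.45 (adjusted p = 0.0173), and Ccl6 fell by 2.14 ± 0.34 (adjusted p = 0.0225). Their median was -0.97 (-0.60 at bounds, -0.82 slide-blocked, -0.96 on slide 2; camera adjusted p = 0.000483), adjusted p = 0.244 with an estimated correlation. Of 26 scavenger and phagocytic receptors, Cd93 fell by 2.80 ± 0.40 (adjusted p = 0.0173) and 25 were not called (2 rises and 7 falls adjusted over the list alone, 1 and 3 without IL-4 replicate 1). Their median was -0.33 (-0.43 slide-blocked, -0.50 on slide 2; camera adjusted p = 0.00263), adjusted p = 0.244 with an estimated correlation. No gene of the cell cycle list was called by limma over all genes, 2 fell without IL-4 replicate 1, 16 of 34 fell when adjusted over the list alone, and 33 of 34 had a value below 0. Their median was -0.69 (-0.58 slide-blocked, -0.68 on slide 2; camera adjusted p = 4.02e-16), adjusted p = 0.244 with an estimated correlation. Ccnd1, cyclin D1, was at -0.85 (adjusted p = 0.453).

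No interferon-stimulated gene was called by limma over all genes or over the list alone, but 5 fell without IL-4 replicate 1, and 35 of 39 had a value below 0, with Ly6e at -0.18 (adjusted p = 0.98). Their median was -0.78 (-0.99 slide-blocked, -1.06 on slide 2; camera adjusted p = 4.84e-06), adjusted p = 0.69 with an estimated correlation. No NF-kB or toll-like receptor gene was called over all genes (1 rise and 5 falls adjusted over the list alone, 1 and 2 without IL-4 replicate 1), with Cd14 at -0.22 (adjusted p = 0.906). Their median was -0.34 (-0.43 slide-blocked, -0.31 on slide 2; camera adjusted p = 0.000442), adjusted p = 0.244 with an estimated correlation. The other 13 lists did not pass. MHC class I genes had a median of -0.28 (adjusted p = 0.11, 0.0413 with slide blocked and 0.0131 without IL-4 replicate 1; in the latter 2 adjusted p = 0.673 and adjusted p = 0.546 with an estimated correlation), and for glycolysis the median was -0.04 where the mean was 0.08 and the test higher. Of the panel, Mrc1 was at -3.45 (adjusted p = 0.0582), Il1b at -2.08 (adjusted p = 0.259) and Tnf at -0.30 (adjusted p = 0.799). Il6 and Arg1 were each detected on 1 of 3 untreated arrays and on no TGFb array, and Nos2, Chil3 and Retnla on no array of either group. The 35 genes of the IL-4 list were not called (2 rises and 1 fall without IL-4 replicate 1), with Flt1, a VEGF receptor, at 1.40 (adjusted p = 0.197).

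In total limma called 88 genes, 55 higher and 33 lower, 75 of them at least 2-fold. In all 88 the groups did not overlap, as in 17.7% of all genes (10% by chance). Median scaling gave 66, of which 24 were higher and 42 lower. With slide as a block 9 were called, all among the 88, and all 88 kept their sign. Within slide 2, with 1 TGFb array and the spread of the untreated arrays alone, limma called 0, with 740 genes at an unadjusted p under 0.05. Of the 18 named genes that passed, 7 also passed with slide blocked (Clec4a1, Clec4b1, Clec4a3, Ccl9, Cd93, Htr2b and Rgl1). Whichever array was left out, 5 passed (Clec4a1, Clec4b1, Clec4a3, Htr2b and Rgl1). The other 13 missed the threshold without some array, at highest adjusted p-values of 0.0807 to 0.179. In all 6 genes (2 higher) were called without TGFb replicate 3, 8 (3 higher) without TGFb replicate 2, 11 (4 higher) without untreated replicate 1, 43 (19 higher) without untreated replicate 2 and 228 (126 higher) without IL-4 replicate 1.

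LPS/IFNg against untreated cells asked what a proinflammatory stimulus of 16 h changed. Cxcl9 and Cxcl10, chemokines that attract T cells, rose by 9.99 ± 0.51 (SE, adjusted p = 3.47e-07) and 7.83 ± 0.57 (adjusted p = 3.23e-06), and Cxcl9 went from 5.10 ± 0.59 (SD, n = 3), where 1 of 3 arrays detected it, to 15.08 (n = 2). Upp1, uridine phosphorylase, rose at least 108-fold (adjusted p = 3.57e-09), Serpina3f, a serine protease inhibitor, at least 113-fold (adjusted p = 1.14e-06) and Dnase1l3, a secreted DNase, at least 86.3-fold (adjusted p = 0.000388). Nos2, the inducible nitric oxide synthase, rose at least 19.3-fold (adjusted p = 1.14e-06), Tnf by 5.78 ± 0.31 (adjusted p = 4.39e-07), Il6 by 5.09 ± 0.23 (adjusted p = 1.49e-07; 1 of 3 untreated arrays detected it) and Il1b by 2.37 ± 0.80 (adjusted p = 0.0357). Hpgd, which inactivates prostaglandins, fell at least 114-fold (adjusted p = 1.02e-07), the organic anion transporter Slco2b1 at least 97.1-fold (adjusted p = 1.45e-07), the ribonuclease gene Rnase4 at least 44.2-fold (adjusted p = 2.85e-05) and Man2a2, a Golgi mannosidase, at least 34.7-fold (adjusted p = 4.74e-07). Mrc1 fell by 6.32 ± 0.82 (adjusted p = 0.000147; 1 of 2 stimulated arrays), Sort1, the sorting receptor sortilin, by 6.06 ± 0.50 (adjusted p = 7.2e-06), Gas6, a ligand of Axl and Mertk, by 5.84 ± 0.21 (adjusted p = 4.77e-08), Cx3cr1 by 5.59 ± 0.62 (adjusted p = 5.7e-05) and Tgfbr1 by 2.19 ± 0.23 (adjusted p = 3.22e-05). P2ry12 fell at least 2.72-fold (adjusted p = 0.0141).

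Of 24 cytokines and effectors, 19 rose and 5 were not called (21 rises adjusted over the list alone), among them Cd40, a costimulatory receptor, by 7.43 ± 0.78 (adjusted p = 3.8e-05), and Lcn2, an iron-siderophore binder, by 7.33 ± 0.62 (adjusted p = 8.69e-06; 1 of 3 untreated arrays detected it). Their median was 2.70 (2.58 at bounds, 2.61 slide-blocked, 2.73 on slide 2), with an adjusted p of 4.47e-13 by camera and of 0.0324 with an estimated correlation. Of 39 interferon-stimulated genes, 34 rose and 5 were not called (35 rises adjusted over the list alone), among them the guanylate-binding proteins Gbp2, by 6.76 ± 0.99 (adjusted p = 0.000352), and Gbp5, at least 56.6-fold (adjusted p = 2.34e-06). Their median was 2.76 (2.64 slide-blocked, 2.75 on slide 2; camera adjusted p = 1.41e-13), adjusted p = 0.347 with an estimated correlation. Of 16 MHC class I genes, 15 rose and 1 was not called (15 rises adjusted over the list alone), among them the peptide transporter Tap1 by 4.01 ± 0.52 (adjusted p = 0.000148) and Nlrc5, a transactivator of this class, by 3.62 ± 0.52 (adjusted p = 0.000293). Their median was 1.92 (1.97 slide-blocked, 1.82 on slide 2; camera adjusted p = 1.43e-07), adjusted p = 0.235 with an estimated correlation. Of 11 MHC class II genes, 8 rose, 1 fell and 2 were not called (9 and 1 adjusted over the list alone). H2-Ab1 rose by 5.79 ± 0.48 (adjusted p = 8.26e-06), H2-Eb1 by 6.14 ± 0.38 (adjusted p = 1.21e-06; 1 of 3 untreated arrays), and the protease Ctss fell by 0.89 ± 0.27 (adjusted p = 0.0225). Their median was 1.83 (1.21 at bounds, 1.92 slide-blocked, 1.89 on slide 2; camera adjusted p = 0.000196), adjusted p = 0.245 with an estimated correlation.

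Of 18 chemokines, 11 rose, 2 fell and 5 were not called (12 and 2 adjusted over the list alone); the falls were Cxcl14 by 4.13 ± 0.61 (adjusted p = 0.000366) and Ccl6 by 2.44 ± 0.38 (adjusted p = 0.000527). Their median was 3.00 (2.85 slide-blocked, 2.73 on slide 2; camera adjusted p = 0.000764), adjusted p = 0.235 with an estimated correlation. Of 32 NF-kB and toll-like receptor genes, 23 rose, 6 fell and 3 were not called (23 and 6 adjusted over the list alone). Traf1, a TNF receptor adaptor, rose by 6.85 ± 0.60 (adjusted p = 1.11e-05; 1 of 3 untreated arrays detected it), Socs3, a suppressor of cytokine signalling, by 4.10 ± 1.20 (adjusted p = 0.0186), while Tlr2 fell by 2.49 ± 0.47 (adjusted p = 0.00168) and Tlr13, a receptor for bacterial RNA, by 2.23 ± 0.52 (adjusted p = 0.00564). Their median was 1.72 (1.69 at bounds, 1.62 slide-blocked, 1.78 on slide 2; camera adjusted p = 1.03e-06), adjusted p = 0.173 with an estimated correlation. Of 21 glycolysis and hypoxia genes, 11 rose and 10 were not called (11 rises adjusted over the list alone), among them the phosphofructokinase Pfkp by 2.46 ± 0.22 (adjusted p = 1.46e-05) and the hexokinase Hk3 by 2.24 ± 0.41 (adjusted p = 0.00135). Their median was 0.83 (0.76 slide-blocked, 0.46 on slide 2; camera adjusted p = 0.00121), adjusted p = 0.411 with an estimated correlation, and camera gave 0.0551 without LPS/IFNg replicate 1. Of 22 unfolded protein and heat shock genes, 9 rose and 13 were not called (9 rises adjusted over the list alone), among them the chaperone Hspa1a, at least 3.16-fold (adjusted p = 1.16e-05), and Trib3, a pseudokinase of the stress response, by 2.14 ± 0.39 (adjusted p = 0.00145; 2 of 3 untreated arrays). Their median was 0.75 (0.69 at bounds, 0.65 slide-blocked, 0.59 on slide 2; camera adjusted p = 0.00144), adjusted p = 0.185 with an estimated correlation.

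Of 35 homeostatic microglia markers, 23 fell, 2 rose and 10 were not called (24 and 3 adjusted over the list alone); the rises were Aif1, the microglial calcium-binding protein Iba1, by 1.32 ± 0.26 (adjusted p = 0.00227) and the phagocytic receptor Mertk by 1.11 ± 0.29 (adjusted p = 0.0101). Their median was -1.74 (-1.41 at bounds, -1.65 slide-blocked, -1.83 on slide 2; camera adjusted p = 1.78e-06), adjusted p = 0.235 with an estimated correlation. Of 34 cell cycle genes, 18 fell, 3 rose and 13 were not called (18 and 3 adjusted over the list alone). Cenpa, a centromeric histone, fell by 4.38 ± 0.29 (adjusted p = 1.63e-06) and Prc1, a factor of cytokinesis, at least 5.07-fold (adjusted p = 0.000123), while Ccne1, cyclin E, rose at least 3.24-fold (adjusted p = 3.17e-05) and the spindle factor Tpx2 by 1.44 ± 0.33 (adjusted p = 0.00493; 1 of 3 untreated arrays detected it). Their median was -0.97 (-0.81 at bounds, -0.95 slide-blocked, -1.03 on slide 2; camera adjusted p = 0.00121), adjusted p = 0.555 with an estimated correlation. Of 16 cholesterol synthesis genes, 7 fell and 9 were not called (8 falls adjusted over the list alone), among them the enzymes Dhcr7, at least 3.67-fold (adjusted p = 0.000123), and Sqle, by 1.95 ± 0.42 (adjusted p = 0.00367). Their median was -0.91 (-0.92 slide-blocked, -1.07 on slide 2; camera adjusted p = 0.0246), adjusted p = 0.411 with an estimated correlation, and camera gave 0.058 without untreated replicate 1. Of 33 lysosomal and damage-associated genes, 17 fell, 5 rose and 11 were not called (17 and 5 adjusted over the list alone). Timp2, a metalloprotease inhibitor, fell by 4.28 ± 0.18 (adjusted p = 1.02e-07) and Trem2, a lipid receptor of microglia, by 4.02 ± 0.25 (adjusted p = 1.36e-06), while Ch25h, cholesterol 25-hydroxylase, rose by 4.11 ± 0.85 (adjusted p = 0.00293) and the cystatin Cst7 by 3.44 ± 0.64 (adjusted p = 0.00157). Their median was -0.78 (-0.84 slide-blocked, -0.79 on slide 2; camera adjusted p = 0.0154), adjusted p = 0.411 with an estimated correlation, and camera gave 0.232 with median scaling.

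The other 8 lists did not pass. Of 28 TGF-beta targets, 3 rose and 11 fell (median -0.56, adjusted p = 0.223), with Gadd45b, a stress-induced growth arrest protein, up by 4.52 ± 0.30 (adjusted p = 1.63e-06; 2 of 3 untreated arrays detected it), the ubiquitin ligase Smurf1 up at least 2.32-fold (adjusted p = 0.00438) and the matrix protein Tgfbi down, where it fell by 4.13 ± 0.91 (adjusted p = 0.00426). Of the 35 genes of the IL-4 list, 7 rose, including Slc7a2 at least 61.9-fold (adjusted p = 2.56e-06) and Il1rn, the IL-1 receptor antagonist, by 6.54 ± 0.77 (adjusted p = 8.13e-05; 2 of 3 untreated arrays), and 3 fell, including the nuclear receptor Pparg at least 5.38-fold (adjusted p = 0.00398). Of 26 scavenger receptors 6 rose and 8 fell, of 29 oxidative phosphorylation genes 7 and 2, of 18 NRF2 genes 1 and 6, and of 20 matrix genes 2 and 1 (median -0.13, mean 0.08, tested higher with adjusted p = 0.607). Of 7 astrocyte markers 1 fell, of 6 oligodendrocyte markers 2 rose and 1 fell, and of 3 neuron markers 1 rose and 1 fell. None of 4 fibroblast and mural cell markers or 2 endothelial markers was called by limma. The 1 tested leukocyte marker, S100a8, rose by 1.51 (adjusted p = 0.0113; 2 of 3 untreated arrays) and was named after its value was seen, and 0 of 7 erythroid markers were tested. Arg1 was detected on 1 of 3 untreated arrays and on neither LPS/IFNg array, and Chil3 and Retnla on none of either group.

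**Figure D2:**
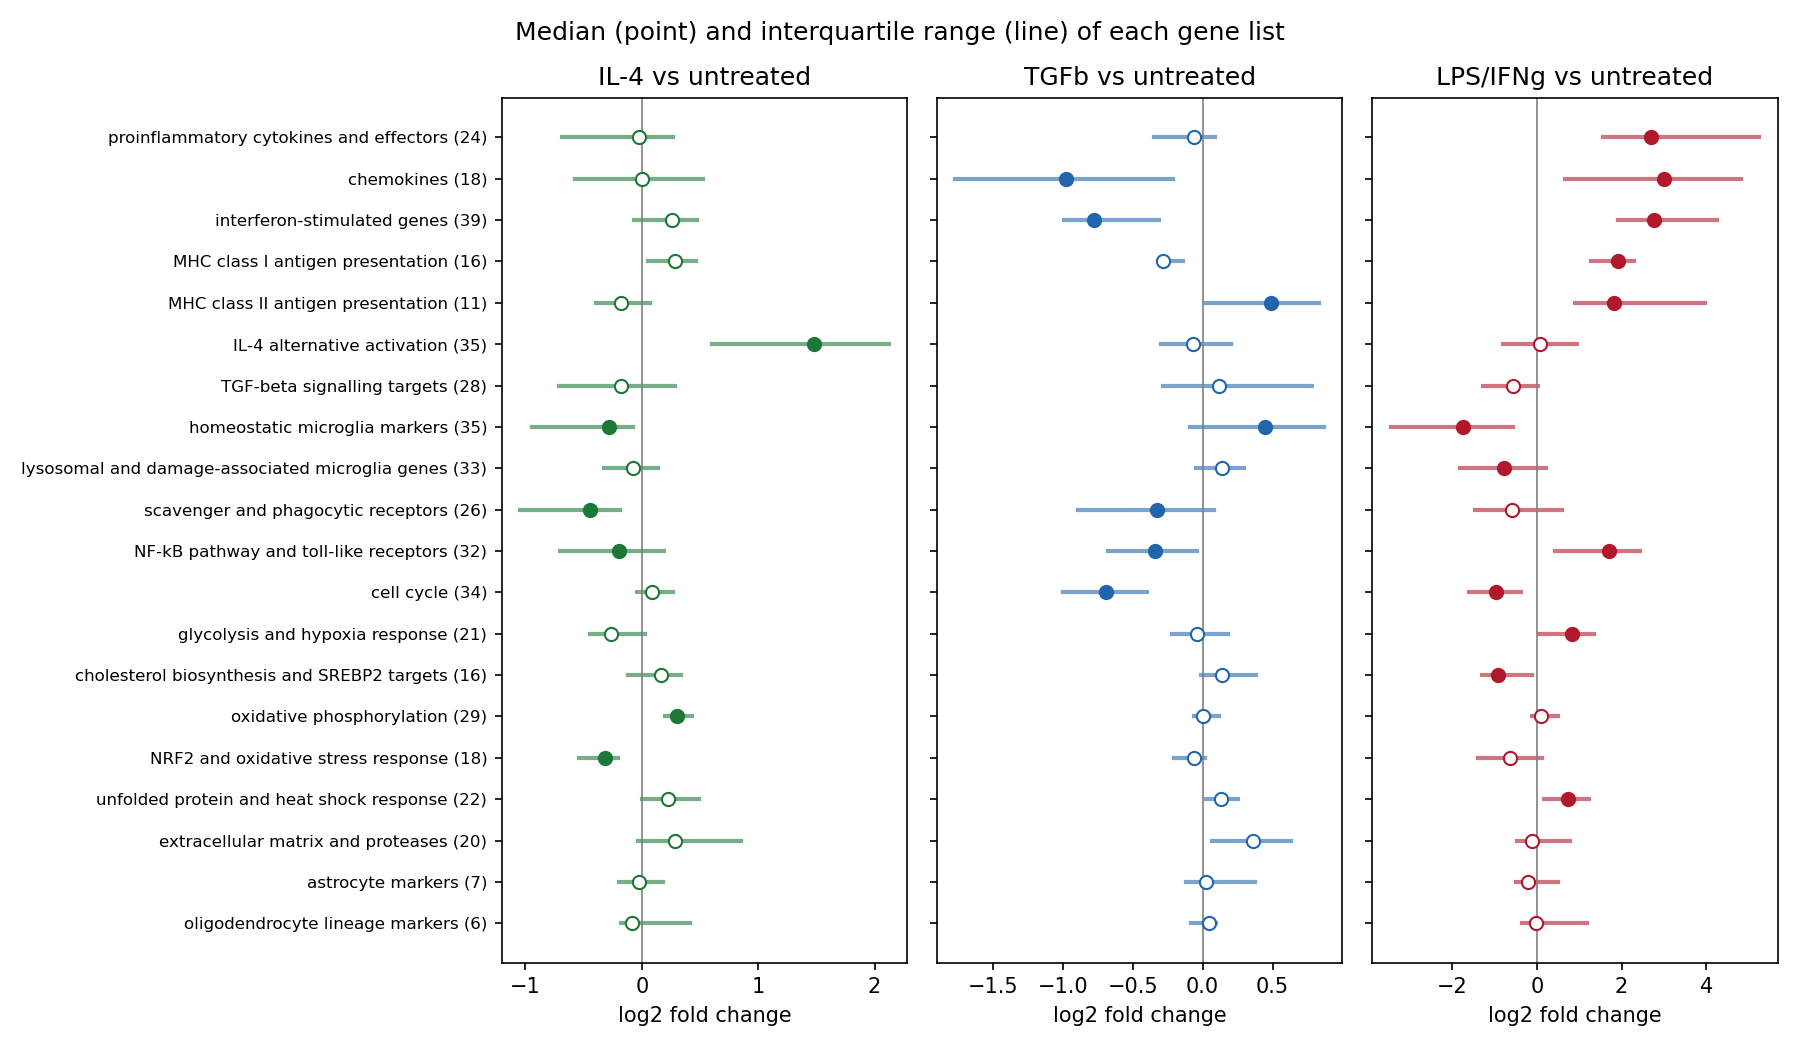
Median log2 fold change against untreated cells (horizontal axis), with the interquartile range of the tested members, for the gene lists (vertical axis) under each of the 3 stimuli. Filled points mark lists that camera called with the preset correlation: 6 with IL-4, 7 with TGFb and 12 with LPS/IFNg, against 2, 0 and 1 with an estimated correlation.

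In total limma called 3674 genes, 1568 higher and 2106 lower, 2186 of them at least 2-fold. In 3667 of these the groups did not overlap, as in 63.1% of all genes (20% by chance). Median scaling moved the median of all genes to -0.25 and gave 3333 genes, of which 1011 were higher and 2322 lower. Relative to that shift no called list changed sign in any comparison. With slide as a block 3322 were called, 3184 of them among the 3674, and within slide 2, with 1 LPS/IFNg array and the spread of the untreated arrays alone, limma called 2270. Of the 56 named genes that passed, 54 also passed with slide blocked, all but Il1b (adjusted p = 0.0946) and Socs3 (adjusted p = 0.0501). Whichever array was left out, 48 passed, and Il1b, Socs3, Mertk, P2ry12, Tgfbi, Tlr13, Tpx2 and Ctss missed the threshold at highest adjusted p-values of 0.0608 to 0.154. The time also differed between LPS/IFNg and the other stimuli.

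IL-4 against TGFb set the 48 h stimuli against each other. Arg1 was at least 212-fold higher with IL-4 (adjusted p = 0.000212), Retnla at least 135-fold (adjusted p = 5.04e-06) and Rnase2a at least 34.3-fold (adjusted p = 6.07e-05). Clec4a1 was higher by 5.58 ± 0.52 (SE, adjusted p = 0.000286), at 11.66 ± 0.89 (SD, n = 3) against 6.08 ± 0.49 (SD, n = 3), and Mrc1 by 5.18 ± 0.73 (adjusted p = 0.00236). With IL-4, Igfbp5 was lower at -5.27 ± 0.66 (adjusted p = 0.00117; 2 of 3 IL-4 arrays detected it), Chst1, a sulfotransferase, at -4.93 ± 0.64 (adjusted p = 0.0015), Gpr84, a receptor for medium-chain fatty acids, at -3.74 ± 0.65 (adjusted p = 0.00635), the prolyl hydroxylase Egln3 at -3.69 ± 0.58 (adjusted p = 0.00405; 2 of 3 IL-4 arrays) and Slamf9 at -3.51 ± 0.59 (adjusted p = 0.00547).

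Of the 35 genes of the IL-4 list, 18 were higher with IL-4, 3 lower and 14 not called (21 and 3 adjusted over the list alone), with Il13ra1 at -2.97 ± 0.44 (adjusted p = 0.00296) and Ch25h at -3.27 ± 0.76 (adjusted p = 0.0242) among the lower. Their median was 1.41 (0.83 at bounds, 1.51 on slide 2), with an adjusted p of 9.58e-12 by camera and of 0.0208 with an estimated correlation. Of 34 cell cycle genes, 13 were higher and 21 not called (18 higher adjusted over the list alone), among them the replication factor Mcm5 at 1.85 ± 0.38 (adjusted p = 0.014) and the thymidine kinase Tk1 at 1.94 ± 0.48 (adjusted p = 0.0326; 1 of 3 TGFb arrays detected it). Their median was 0.89 (1.20 on slide 2; camera adjusted p = 9.58e-12), adjusted p = 0.334 with an estimated correlation. Of 35 homeostatic markers, 11 were lower and 24 not called (14 lower adjusted over the list alone), among them Olfml3, a secreted microglial glycoprotein, at -3.23 ± 0.43 (adjusted p = 0.00188) and Cx3cr1 at -3.21 ± 0.56 (adjusted p = 0.00635). Their median was -0.65 (-0.57 on slide 2; camera adjusted p = 2.71e-07), adjusted p = 0.334 with an estimated correlation. Of 28 TGF-beta targets, 8 were lower, 2 higher and 18 not called (10 and 6 adjusted over the list alone), with Pmepa1 at -2.79 ± 0.46 (adjusted p = 0.00502), Spsb1 at -2.43 ± 0.31 (adjusted p = 0.0015) and Gadd45b at 1.53 ± 0.26 (adjusted p = 0.00628; 1 of 3 TGFb arrays). The other higher gene, Tgfb3, a ligand of the pathway, was at least 1.55-fold higher (adjusted p = 0.0209). Their median was -0.56 (-0.32 on slide 2, -0.35 without IL-4 replicate 1; camera adjusted p = 0.00981), adjusted p = 0.334 with an estimated correlation.

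Of 29 oxidative phosphorylation genes, 2 were higher, Cyc1 at 0.60 ± 0.14 (adjusted p = 0.0292) and the complex I subunit Ndufv1 at 0.57 ± 0.15 (adjusted p = 0.0379), and 27 were not called (3 higher adjusted over the list alone). Their median was 0.24 (0.29 on slide 2; camera adjusted p = 0.000351), adjusted p = 0.334 with an estimated correlation. Of 11 MHC class II genes, 3 were lower, 1 higher and 7 not called (7 and 1 adjusted over the list alone), with H2-Ob at least 5.3-fold lower (adjusted p = 0.000334), the peptide loading factor H2-DMa at -2.13 ± 0.47 (adjusted p = 0.0193) and the invariant chain Cd74 at 3.90 ± 0.56 (adjusted p = 0.00256). Their median was -0.65 (-0.61 on slide 2; camera adjusted p = 0.0114), adjusted p = 0.534 with an estimated correlation.

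The calls of 4 lists were lost without IL-4 replicate 1. Of 39 interferon-stimulated genes, 2 were higher, the transcription factor Irf1 at 1.45 ± 0.34 (adjusted p = 0.0259) and Ifi204 at 1.17 ± 0.27 (adjusted p = 0.0252; 1 of 3 TGFb arrays detected it), 1 was lower, Irf8 at -1.26 ± 0.29 (adjusted p = 0.0232), and 36 were not called (2 and 1 adjusted over the list alone, 1 and 0 by limma without the array). Their median was 0.96 (0.84 on slide 2; camera adjusted p = 1.77e-05), adjusted p = 0.642 with an estimated correlation, and 0.17 without the array (camera adjusted p = 0.191). Of 16 MHC class I genes, H2-D1 was higher at 0.56 ± 0.15 (adjusted p = 0.0483) and 15 were not called (0 called by limma adjusted over the list alone, with slide blocked or without the array). Their median was 0.47 (0.26 on slide 2; camera adjusted p = 0.0105), adjusted p = 0.612 with an estimated correlation, and 0.23 without the array (camera adjusted p = 0.262). Of 18 chemokines, 4 were higher, 1 lower and 13 not called (4 and 1 adjusted over the list alone), with Ccl24 at least 17.9-fold (adjusted p = 0.00135) and the monocyte attractant Ccl7 at least 17.1-fold higher (adjusted p = 0.0304) and Cxcl14 at -3.20 ± 0.55 (adjusted p = 0.00594). Their median was 0.69 (0.59 at bounds, 0.41 on slide 2; camera adjusted p = 0.0302), adjusted p = 0.519 with an estimated correlation, and 0.27 without the array (camera adjusted p = 0.168). Camera lost it also with median scaling (adjusted p = 0.104), without background correction (0.0772), without a filter (0.052), in the authors' table (0.0869) and without TGFb replicate 3 (0.0764). Of 33 lysosomal and damage-associated genes, 5 were lower, 1 higher and 27 not called (6 and 2 adjusted over the list alone), with the tetraspanin Cd9 at -1.61 ± 0.40 (adjusted p = 0.034) and Ccl6 at 1.56 ± 0.34 (adjusted p = 0.0187). Their median was -0.18 (-0.16 on slide 2; camera adjusted p = 0.0335), adjusted p = 0.571 with an estimated correlation, and camera gave 0.11 without the array, 0.153 without TGFb replicate 2 and 0.0716 without TGFb replicate 3.

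The other 10 lists did not pass, though without IL-4 replicate 1 camera called the matrix genes (median -0.41, adjusted p = 0.0303, and adjusted p = 0.535 with an estimated correlation). Of 24 cytokines and effectors, Cd40 was higher at 2.55 ± 0.70 (adjusted p = 0.049; 2 of 3 TGFb arrays detected it) and Tnf lower at -1.13 ± 0.27 (adjusted p = 0.0299), with 22 not called. Among markers of other cell types, chosen after their values were seen, limma called Pecam1 of endothelium (3.37; 1 of 3 TGFb arrays) and Rbfox3 of neurons (at least 1.4-fold) higher, and S100a8 of leukocytes (at least 5.35-fold), Cspg4 and Mbp of oligodendrocytes (-2.27, with 2 of 3 IL-4 arrays, and -0.78), Ndrg2 of astrocytes (-1.97; 1 of 3 IL-4 arrays) and Eno2 of neurons (-0.98) lower. Median, mean and test differed in sign for NF-kB genes (0.16, -0.01, higher) and cholesterol synthesis (0.01, -0.09, lower).

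**Figure D3:**
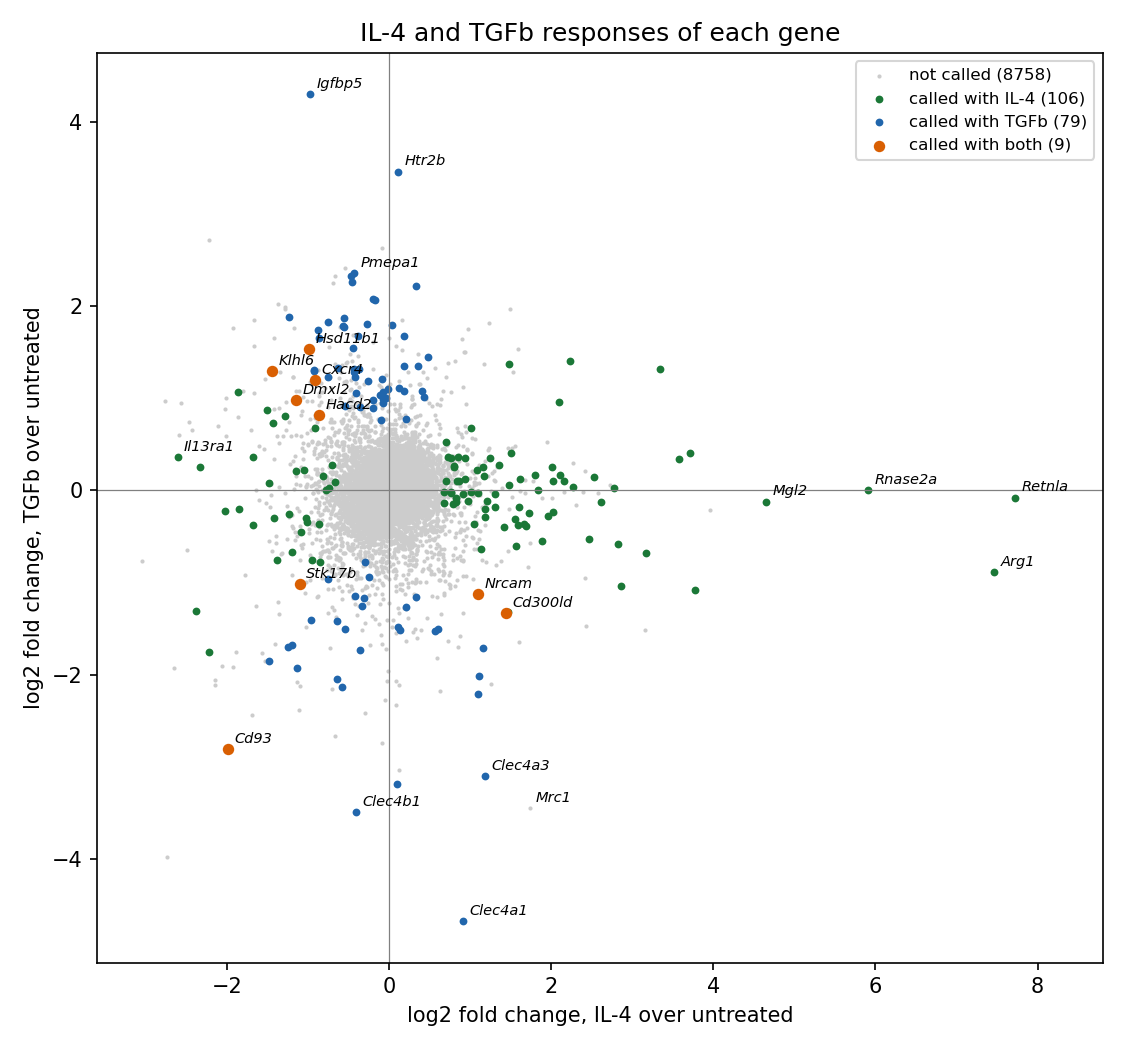
Log2 fold change of each of the 8952 genes against untreated cells, with IL-4 on the horizontal and TGFb on the vertical axis, 1 point per gene. Colours mark the 106 genes called only with IL-4, the 79 called only with TGFb and the 9 called with both.

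In total limma called 768 genes, 351 higher and 417 lower with IL-4, 469 of them at least 2-fold. In all 768 the groups did not overlap, as in 27.3% of all genes (10% by chance). Median scaling moved the median of all genes to 0.17 and gave 645 genes, of which 431 were higher and 214 lower. With slide as a block 682 were called, 662 of them among the 768, and the list medians did not move. Within a single slide limma called 3 on slide 2, with 1 array of each and the spread of the untreated arrays alone, and 27 on slide 1, with 2 of each. Of the 36 named genes, 33 passed with slide blocked, all but Cd40 (adjusted p = 0.0673), H2-D1 (adjusted p = 0.0601) and Ndufv1 (adjusted p = 0.0524). Whichever array was left out, 20 passed, and 16 missed the threshold without some array, at highest adjusted p-values of 0.0581 to 0.172. In all 391 genes were called without TGFb replicate 2 and 464 without TGFb replicate 3.

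LPS/IFNg against IL-4 set the 16 h stimulus against alternative activation at 48 h. Cxcl9 was higher with LPS/IFNg by 9.47 ± 0.51 (SE, adjusted p = 5.12e-07), at 15.08 (n = 2) against 5.61 ± 1.01 (SD, n = 3), where 2 of 3 arrays detected it. Cxcl10 was higher by 9.36 ± 0.57 (adjusted p = 1.2e-06; 2 of 3 IL-4 arrays), Tnf by 7.20 ± 0.31 (adjusted p = 1.15e-07) and Upp1 at least 109-fold (adjusted p = 3.7e-09). Arg1 was lower at least 183-fold (adjusted p = 2.24e-05) and Retnla at least 116-fold (adjusted p = 5.5e-07). Mrc1 was lower at -8.05 ± 0.82 (adjusted p = 3.3e-05; 1 of 2 LPS/IFNg arrays detected it).

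Of 24 cytokines and effectors, 21 were higher and 3 not called (21 higher adjusted over the list alone). Their median was 3.42 (3.29 at bounds, 3.48 slide-blocked, 3.74 on slide 2), with an adjusted p of 4.23e-14 by camera and of 0.0252 with an estimated correlation. Of 39 interferon-stimulated genes, 35 were higher and 4 not called (37 higher adjusted over the list alone). Their median was 2.58 (2.66 slide-blocked, 3.28 on slide 2; camera adjusted p = 4.23e-14), adjusted p = 0.272 with an estimated correlation. Of 32 NF-kB genes, 23 were higher, 4 lower and 5 not called (24 and 5 adjusted over the list alone), with the endosomal receptor Tlr8 at -1.92 ± 0.32 (adjusted p = 0.000852). Their median was 1.81 (1.85 slide-blocked, 1.89 on slide 2; camera adjusted p = 6.2e-09), adjusted p = 0.0812 with an estimated correlation. Of 16 MHC class I genes, 13 were higher and 3 not called (14 higher adjusted over the list alone). Their median was 1.61 (1.62 slide-blocked, 1.53 on slide 2; camera adjusted p = 4.72e-07), adjusted p = 0.272 with an estimated correlation. Of 11 MHC class II genes, 9 were higher and 2 not called (9 higher and 1 lower adjusted over the list alone). Their median was 1.64 (1.22 at bounds, 1.61 slide-blocked, 1.51 on slide 2; camera adjusted p = 4.22e-05), adjusted p = 0.265 with an estimated correlation. Of 18 chemokines, 9 were higher, 2 lower and 7 not called (11 and 3 adjusted over the list alone). Their median was 2.44 (2.48 slide-blocked, 3.65 on slide 2; camera adjusted p = 0.000747), adjusted p = 0.265 with an estimated correlation.

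Of 21 glycolysis and hypoxia genes, 11 were higher and 10 not called (13 higher adjusted over the list alone). Their median was 1.00 (1.02 slide-blocked, 0.66 on slide 2; camera adjusted p = 1.67e-05), adjusted p = 0.272 with an estimated correlation. Of 22 unfolded protein and heat shock genes, 7 were higher, 1 lower and 14 not called (6 and 1 adjusted over the list alone), with the disulfide isomerase Pdia4 at -0.98 ± 0.28 (adjusted p = 0.0173). Their median was 0.46 (0.46 slide-blocked, 0.36 on slide 2; camera adjusted p = 0.0134), adjusted p = 0.265 with an estimated correlation. Of 34 cell cycle genes, 20 were lower, 4 higher and 10 not called (22 and 4 adjusted over the list alone). Their median was -1.29 (-1.06 at bounds, -1.32 slide-blocked, -1.62 on slide 2; camera adjusted p = 0.000261), adjusted p = 0.481 with an estimated correlation. Of 35 homeostatic markers, 20 were lower, 3 higher and 12 not called (21 and 3 adjusted over the list alone), with Aif1 at 1.71 ± 0.26 (adjusted p = 0.000464). Their median was -0.97 (-0.94 slide-blocked, -1.04 on slide 2; camera adjusted p = 0.000261), adjusted p = 0.272 with an estimated correlation. Of 16 cholesterol synthesis genes, 8 were lower and 8 not called (8 lower adjusted over the list alone). Their median was -0.79 (-0.80 slide-blocked, -1.08 on slide 2; camera adjusted p = 0.013), adjusted p = 0.331 with an estimated correlation. Of the 35 genes of the IL-4 list, 19 were lower with LPS/IFNg, 7 higher and 9 not called (19 and 7 adjusted over the list alone). Their median was -1.06 (-0.98 at bounds, -1.13 slide-blocked, -1.17 on slide 2; camera adjusted p = 0.0231), adjusted p = 0.272 with an estimated correlation, and camera gave 0.0743 without background correction, 0.0676 with median scaling and 0.0974 in the authors' table. Without IL-4 replicate 1, in which the interferon-stimulated genes averaged 9.78 and the chemokines 9.07 (7.46 and 7.77 in the other IL-4 arrays), the medians were 3.53 and 3.43 for these lists, 3.75 for cytokines, 1.22 for MHC class II, -1.58 for cell cycle and -1.36 for the IL-4 list.

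In total limma called 3577 genes, 1470 higher and 2107 lower, 2125 of them at least 2-fold. In 3568 the groups did not overlap, as in 61.0% of all genes (20% by chance). Median scaling moved the median of all genes to -0.32 and gave 3418 genes, of which 912 were higher and 2506 lower. With slide as a block 3504 were called, 3398 of them among the 3577, and limma called 1502 within slide 2 and 834 within slide 1, each with 1 LPS/IFNg array and the spread of other groups. All 44 named genes passed with slide blocked and 39 whichever array was left out, while Tpx2, Trib3, Pdia4, the transcription factor Bhlhe40 and Tgfbi missed the threshold at highest adjusted p-values of 0.0535 to 0.323. Without LPS/IFNg replicate 3 limma called 2358 genes. The 8 other lists did not pass. Of markers of other cell types, named after their values were seen, limma called Mag, Eno2 and S100a8 higher and Mbp, Syp and Rbfox3 lower. Lysosomal and damage-associated genes had a median of -0.63 (adjusted p = 0.0537), and were called with replicate number as a block (adjusted p = 0.0444, and adjusted p = 0.433 with an estimated correlation) and without IL-4 replicate 1 (-0.75, adjusted p = 0.0241, and adjusted p = 0.463 with an estimated correlation), and for matrix genes the median of -0.59 and mean of -0.24 stood beside a test higher (adjusted p = 0.934).

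LPS/IFNg against TGFb set the 16 h stimulus against the other 48 h stimulus. Cxcl9 was higher with LPS/IFNg by 10.33 ± 0.51 (SE, adjusted p = 2.31e-07), at 15.08 (n = 2) against 4.75 ± 0.40 (SD, n = 3), where 1 of 3 arrays detected it. Cxcl10 was higher by 9.67 ± 0.57 (adjusted p = 7.65e-07; 1 of 3 TGFb arrays) and Mmp13, a collagenase, by 8.09 ± 0.43 (adjusted p = 3.35e-07). Slco2b1 was lower at least 186-fold (adjusted p = 7.94e-08) and Olfml3 at -6.66 ± 0.48 (adjusted p = 2.84e-06) and Cx3cr1 at -6.33 ± 0.62 (adjusted p = 2.07e-05).

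Of 39 interferon-stimulated genes, 36 were higher and 3 not called (37 higher adjusted over the list alone). Their median was 3.86 (3.71 at bounds, 3.99 slide-blocked, 4.28 on slide 2; camera adjusted p = 6.75e-16), adjusted p = 0.323 with an estimated correlation. Of 24 cytokines and effectors, 20 were higher, 1 lower (the cytokine Osm, at -1.41 ± 0.31, adjusted p = 0.00388) and 3 not called (21 and 1 adjusted over the list alone). Their median was 3.80 (3.47 at bounds, 3.88 slide-blocked, 4.04 on slide 2), with an adjusted p of 1.66e-12 by camera and of 0.0369 with an estimated correlation. Of 18 chemokines, 13 were higher, 1 lower (Cxcl14 at -4.74 ± 0.61, adjusted p = 0.000126) and 4 not called (13 and 1 adjusted over the list alone). Their median was 3.91 (3.60 at bounds, 3.91 slide-blocked, 3.89 on slide 2; camera adjusted p = 1.54e-05), adjusted p = 0.142 with an estimated correlation. Of 32 NF-kB genes, 24 were higher, 5 lower and 3 not called (24 and 6 adjusted over the list alone). Their median was 2.05 (2.07 slide-blocked, 2.01 on slide 2; camera adjusted p = 5.02e-08), adjusted p = 0.111 with an estimated correlation. Of 16 MHC class I genes, 14 were higher and 2 not called (16 higher adjusted over the list alone). Their median was 2.11 (2.13 slide-blocked, 1.83 on slide 2; camera adjusted p = 4.81e-08), adjusted p = 0.212 with an estimated correlation. Of 11 MHC class II genes, 6 were higher, 2 lower and 3 not called (6 and 2 adjusted over the list alone), with H2-Ob at -1.62 ± 0.28 (adjusted p = 0.000902). Their median was 1.17 (1.13 at bounds, 1.24 slide-blocked, 1.38 on slide 2; camera adjusted p = 0.016), adjusted p = 0.401 with an estimated correlation.

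Of 35 homeostatic markers, 25 were lower, 2 higher and 8 not called (25 and 2 adjusted over the list alone). Their median was -2.43 (-1.84 at bounds, -2.35 slide-blocked, -2.49 on slide 2; camera adjusted p = 1.09e-07), adjusted p = 0.183 with an estimated correlation. Of 33 lysosomal and damage-associated genes, 15 were lower, 2 higher and 16 not called (15 and 2 adjusted over the list alone). Their median was -0.54 (-0.49 slide-blocked, -0.41 on slide 2; camera adjusted p = 0.00861), adjusted p = 0.4 with an estimated correlation. Of 16 cholesterol synthesis genes, 8 were lower and 8 not called (9 lower adjusted over the list alone). Their median was -1.0 (-0.97 slide-blocked, -0.96 on slide 2; camera adjusted p = 0.0111), adjusted p = 0.4 with an estimated correlation. Of 21 glycolysis and hypoxia genes, 10 were higher, 1 lower (Egln3 at -3.06 ± 0.65, adjusted p = 0.00322) and 10 not called (11 and 1 adjusted over the list alone). Their median was 0.69 (0.68 slide-blocked, 0.33 on slide 2; camera adjusted p = 0.00247), adjusted p = 0.401 with an estimated correlation, and camera gave 0.0804 without LPS/IFNg replicate 1. Of 22 unfolded protein and heat shock genes, 7 were higher and 15 not called (7 higher adjusted over the list alone). Their median was 0.70 (0.61 at bounds, 0.68 slide-blocked, 0.60 on slide 2; camera adjusted p = 0.00761), adjusted p = 0.183 with an estimated correlation. Of 28 TGF-beta targets, 12 were lower and 4 higher (median -0.68, camera adjusted p = 0.124), with Pmepa1 at least 15.9-fold lower (adjusted p = 6.24e-05) and Tgfbi at -4.86 ± 0.91 (adjusted p = 0.00144). Of markers of other cell types, named after their values were seen, limma called Mag, Cnp and Pecam1 higher and Mbp, Cspg4 and Ndrg2 lower.

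**Figure D4:**
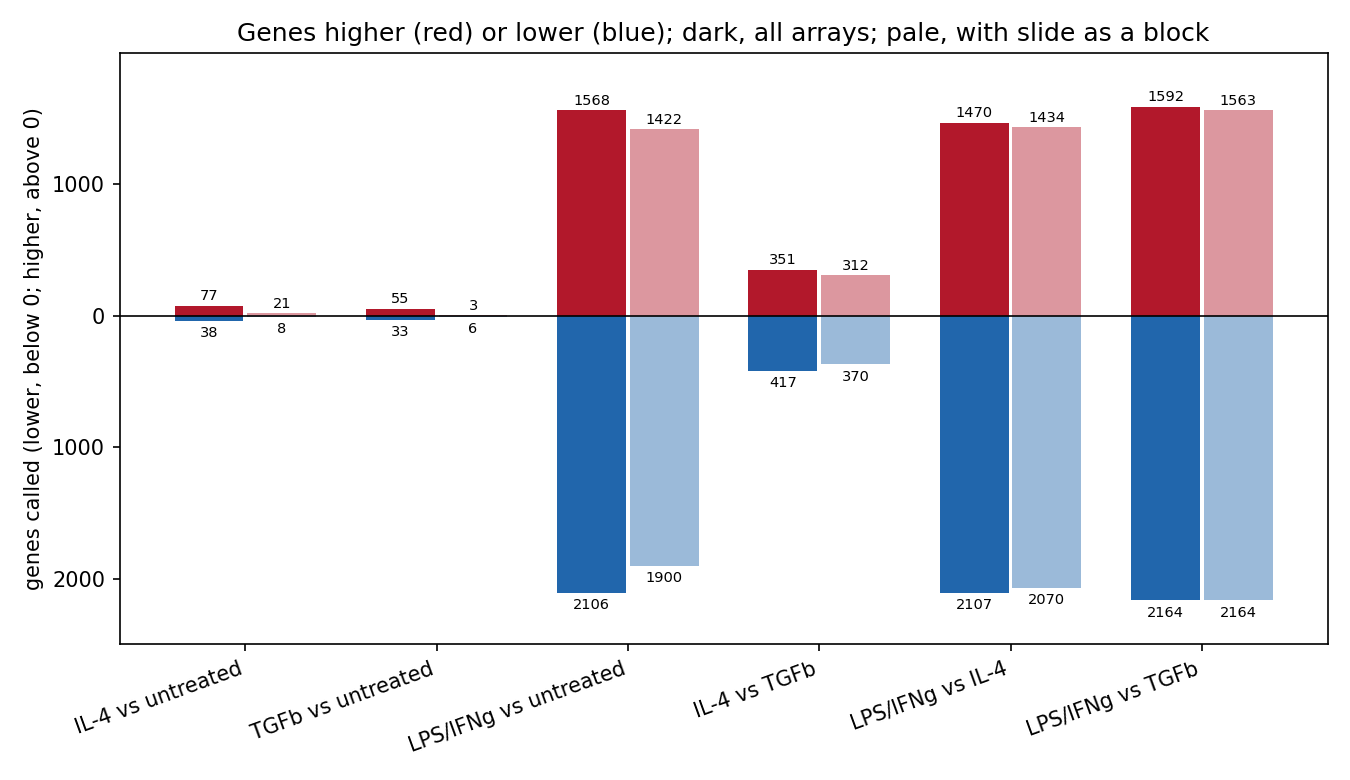
Genes called higher and lower by limma (bars, from 0) in the 6 comparisons, with all arrays in 1 model and with slide as a block.

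In total limma called 3756 genes, 1592 higher and 2164 lower, 2339 of them at least 2-fold. In 3746 the groups did not overlap, as in 64.8% of all genes (20% by chance). With slide as a block 3727 were called, 3611 of them among the 3756, and within slide 2 1761 and within slide 1 1276, again with 1 LPS/IFNg array. All 45 named genes passed with slide blocked and 38 whichever array was left out, while Socs3, Socs2, Npc2, Osm, Fn1, Fcer1g and Cdkn1a missed the threshold at highest adjusted p-values of 0.0511 to 0.115. The list calls that held with an estimated correlation were those of the IL-4 list and the scavenger receptors with IL-4, of the IL-4 list against TGFb, and of the cytokines in the 3 LPS/IFNg comparisons.

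The overlaps of the comparisons with untreated cells asked which genes the stimuli shared. IL-4 and TGFb shared 9 calls. Cd93 fell with both, as did the kinase gene Stk17b (-1.10 and -1.02). Cd300ld, a myeloid receptor (1.45 and -1.33), and the adhesion molecule Nrcam (1.10 and -1.12) rose with IL-4 and fell with TGFb. Klhl6 (-1.44 and 1.29), the chemokine receptor Cxcr4 (-0.91 and 1.19), Dmxl2 (-1.14 and 0.98) and Hacd2, an enzyme of fatty acid elongation (-0.86 and 0.81), fell with IL-4 and rose with TGFb, as did Hsd11b1, a glucocorticoid-activating enzyme (at least 1.29-fold lower, and 1.53). None rose with both in limma, 2 fell with both and 7 moved apart, where independent calls would give 0.473, 0.14 and 0.284 plus 0.233. IL-4 and LPS/IFNg shared 70 calls, 29 higher in both, 24 lower in both, 11 higher with IL-4 only and 6 higher with LPS/IFNg only, against 13.5, 8.94, 18.1 and 6.66 for independent calls. The checkpoint ligand Cd274 (2.09 and 4.34) rose with both, and Tmem176a (-2.38 and -4.20) and Tlr2 (-2.34 and -2.49) fell with both. The lamin gene Lmna (1.59 and -1.37) rose with IL-4 and fell with LPS/IFNg, and Clec4e (-2.23 and 3.66) and Tnf (-1.42 and 5.78) the reverse.

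TGFb and LPS/IFNg shared 59 calls, 4 higher in both, 15 lower in both, 32 higher with TGFb and lower with LPS/IFNg and 8 the reverse, against 9.63, 7.76, 12.9 and 5.78 for independent calls. The serine synthesis gene Psat1 (1.77 and 3.03) rose and Ccl6 (-2.14 and -2.44) fell with both. The kinase gene Sgk1 (1.82 and -2.22) rose with TGFb and fell with LPS/IFNg, as did Pmepa1 (2.36, and at least 3.1-fold lower). Rgl1 (-2.20 and 2.29) fell with TGFb and rose with LPS/IFNg. Simulated unchanged groups with the same controls shared at most 1 call, but without changed genes they set no benchmark. The covariance of log2 fold changes across genes was -0.00121 for IL-4 and TGFb (r = -0.00646), 0.137 for IL-4 and LPS/IFNg (r = 0.251) and -0.0575 for TGFb and LPS/IFNg (r = -0.115), against 0.0354, 0.0353 and 0.0354 in the simulations. The 3 untreated arrays are too few to divide, so part of the shared calls may come from them. With slide blocked the shared calls numbered 0, 19 and 3.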

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

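The 3 tests on IL-4 replicate 1, the test of slide differences and the reading of lost precision by comparison were chosen only after the result was seen.

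Of 2172 detected probes without a single gene name, which the comparisons by gene leave out, limma called 7 higher and 8 lower with IL-4, 7 higher and 7 lower with TGFb, and 322 higher and 375 lower with LPS/IFNg, each against untreated cells. They stand here because only the alternative with every probe includes them, and it does not show them apart. What they measure was not tested.

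The 6 arrays of each pair of groups of 3 allow 10 splits into 3 and 3, so the share of splits can never be under 0.1. For IL-4 against untreated cells 1 split, the real one, gave 115 genes or more, and the highest other gave 2. For TGFb against untreated cells 1 split gave 88 or more and the highest other 2, and for IL-4 against TGFb 1 split gave 768 or more and the highest other 0. These splits are too few to weigh chance. If replicate numbers pair the IL-4 and untreated arrays, which is not established, 4 splits part all 3 pairs. Of these the highest besides the real one gave 0.

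IL-4 replicate 1 stood apart from the other IL-4 arrays. A slide effect is argued against by its correlation of 0.945 with replicate 2 on the same slide, below the 0.987 between replicates 2 and 3 on different slides, and another group's label by 14 of the 15 IL-4 list genes called higher without it, which lay above all untreated arrays in it. Fibroblast or mural cells in that culture could be a source, since 3 of the 4 tested markers lay at least 1 log2 unit above the other 10 arrays, and Col3a1, Tagln and Myl9, at 5.11, 5.29 and 5.73, were detected in it and in 0 of the other 10. That stays open, because Dcn (5.21 against 5.80) and Col1a2 (4.92 against 5.25) were not higher, Gja1 of the astrocyte list (11.2 against 6.08) and Cldn11 of the oligodendrocyte list (8.30 against 5.61) were higher too, and 6 of the 14 markers are also in another list. No other biological explanation was tested, since the labels give none for a single culture.

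Fewer genes passed with slide as a block, 29 in place of 115 with IL-4 and 9 in place of 88 with TGFb. In the calls the median ratio of blocked to unblocked fold changes was 0.997 (IL-4) and 1.02 (TGFb). Within slide 2, from 1 array each, it was 0.946 and 1.03. The calls were picked in these data, so slide differences stay open. Lost precision may account for the TGFb count, since the standard error ratio of 1.19 alone predicted 6 genes against the 9 found. For IL-4 it predicted 16 against 29, so this stays open. Slide terms themselves passed in 0 of 8952 genes in limma, with 519 at an unadjusted p under 0.05 where chance gives 447.6, and no biological explanation was tested.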

How the results depend on the processing

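The alternative with replicate number as a block on the IL-4 and untreated arrays alone, which gave 77 genes, and an estimated correlation together with a block or without IL-4 replicate 1, were chosen only after the result was seen.

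Signals near background limit what can be called, so dim genes are given as bounds, and the few arrays limit precision. The cause was not tested for the differences below unless stated. Among the named genes, over the alternatives, calls were the same in 320 and weaker in 122 with IL-4, in 337 and 113 with TGFb, in 1368 and 28 with LPS/IFNg, in 751 and 185 for IL-4 against TGFb, in 1101 and 40 for LPS/IFNg against IL-4 and in 1127 and 42 against TGFb, and no called gene reversed. Where a group was left with 1 array, as LPS/IFNg without the other, each stimulus on slide 2 and LPS/IFNg on slide 1, that lone sample was assumed to vary like the other groups.

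With the authors' table IL-4 changed 406 genes and TGFb 289, and shared calls were 55 (IL-4 and TGFb), 278 (IL-4 and LPS/IFNg) and 196 (TGFb and LPS/IFNg); by construction the slide term removed there is not counted in the model. Without a filter TGFb changed 56, and shared calls were 3 for IL-4 and TGFb and 31 for TGFb and LPS/IFNg. With every probe in place of 1 per gene, and so more tests, the LPS/IFNg comparisons gave 5822 against untreated cells, 5579 against IL-4 and 6103 against TGFb. Without background correction IL-4 and TGFb shared 15. With median scaling they shared 5, and IL-4 and LPS/IFNg 40. At least 2-fold, these shared 5 and 41.

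With slide blocked, IL-4 changed 29 and TGFb 9, and shared calls were 0, 19 and 3. On slide 2 alone, with fewer arrays, the counts were 3 (IL-4), 0 (TGFb, by limma, with 740 at an unadjusted p under 0.05), 2270 (LPS/IFNg), 3 (IL-4 against TGFb), 1502 (LPS/IFNg against IL-4) and 1761 (against TGFb). On slide 1 alone the latter 3 were 27, 834 and 1276. With replicate number as a block IL-4 changed 184 and TGFb 148, and shared calls were 24, 122 and 97. Array weights gave 477 (IL-4), 289 (TGFb) and 1483 (IL-4 against TGFb), and the arrays of the 2 groups alone, fewer by construction, 18, 40 and 478.

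Lists called fell from 6, 7, 12, 10, 12 and 11 (report order) to 2, 0, 1, 1, 1 and 1 with an estimated correlation. Fry called 3 (IL-4), 0 (TGFb) and 5 (IL-4 against TGFb), and kept all LPS/IFNg list calls.

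Leaving out each array gave 25 to 129 genes with IL-4, 6 to 228 with TGFb, 2642 to 4009 with LPS/IFNg, 391 to 793 for IL-4 against TGFb, 2358 to 3725 for LPS/IFNg against IL-4 and 2780 to 4033 against TGFb. Shared calls were 0 to 14, 14 to 85 and 3 to 159. The IL-4 count was 25 without untreated replicate 1, 32 without untreated replicate 3, 55 without IL-4 replicate 3, 57 without TGFb replicate 2, 62 without either LPS/IFNg array, 68 without TGFb replicate 3, 72 without TGFb replicate 1 and 75 without IL-4 replicate 2. The TGFb count was 6, 8 and 58 without TGFb replicates 3, 2 and 1 and 11 and 43 without untreated replicates 1 and 2. It was 52 and 228 without IL-4 replicates 2 and 1. Without IL-4 replicate 1 the median TGFb fold change was the same while the median SE fell from 0.207 to 0.188. IL-4 against TGFb gave 391 and 464 without TGFb replicates 2 and 3.

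Some genes that were not called changed sign. With IL-4, C1qb was -0.0539 in the authors' table, -0.0536 with slide blocked, -0.0875 with array weights and -0.12 to 0.13 leaving out 1 array, and Fth1 was 0.0213 with median scaling, 0.00789 with slide as a random block, 0.0338 on slide 2 and -0.0338 to 0.0338 leaving out 1 array. Il6 was 0.00583 without background correction, 0.00917 with median scaling, 0.0146 in the authors' table and -0.15 to 0.23 leaving out 1 array. With TGFb, Cx3cr1 was -0.26 on slide 2. Leaving out 1 array gave Arg1 -1.49 to 0.21, Cd14 -0.38 to 0.00602, Il6 -0.25 to 0.14, Ly6e -1.09 to 0.28 and P2ry12 -0.13 to 0.79. With LPS/IFNg, leaving out 1 array gave Arg1 -1.60 to 0.10. Arg1 and Il6 were detected on 1 of 3 untreated arrays, so their signs here lie near background. Panel genes detected on no array of both groups (Nos2 with IL-4, Nos2, Chil3 and Retnla with TGFb, Chil3 and Retnla with LPS/IFNg) have no fold and are left out.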

Other observations

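The scan of gene families and the bootstrap range below were chosen only after the result was seen. Ribosomal protein genes were not a fixed list, but passed in that scan (Rps and Rpl).

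Genes were grouped by symbol stem, and 359 families were compared with all genes, adjusted over the families of a comparison. With TGFb, 3 of 6 Clec4 genes fell where 0.0221 were expected (adjusted p = 0.000325). With LPS/IFNg, 8 of 10 Psmb genes of the proteasome and 6 of 6 Gbp genes rose (adjusted p = 0.00514 each). Of 14 Klhl genes 12 fell (adjusted p = 0.000188). Gm (21 of 52 higher, 5 lower, adjusted p = 0.0102) and Fam (29 of 67 lower, 7 higher, adjusted p = 0.024) passed too. So did Hspa, Psmc, Ifi and Parp, and whether stems mark related genes was not tested. In IL-4 against TGFb, 4 of 7 Mcm genes of DNA replication were higher with IL-4 (adjusted p = 0.0266). No median of these stems changed sign with median scaling, without background correction, in the authors' table or with slide blocked.

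Ribosomal protein genes were lower with LPS/IFNg than in untreated cells. Of 49 tested, 39 fell, 0 rose by limma and 10 were not called, with a median of -0.74 and Rpl22 at -1.34, Rps19 at -1.27 and Rps4x at -1.19; the median was -0.78 within slide 2. A shift of bright genes as a class is argued against, as 0.01% of 10000 random lists matched on mean signal had a median as low (random median -0.20). Normalization between arrays may explain part of it and stays open, since the median relative to all genes was -0.34 with median scaling and -0.67 with quantile normalization, a ratio of 0.504 with a bootstrap 95% range of 0.432 to 0.61. The effect of time could not be tested, since no other stimulus had 16 h and untreated cells have no time given, and signal from pseudogenes was not tested.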
